A study of Mus musculus with 28 samples.

How the data were processed

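Total RNA of CD4+ T cells from 28 samples had been hybridised to Affymetrix HT MG-430 PM arrays, 1 sample per array. The deposited table holds 45141 probe sets per array as linear intensity values, made with RMA per the submitters' processing notes, with the version not given in the sources used here. RMA corrects the background, quantile normalizes the arrays and summarises the probes of a set. Because the deposited intensity values were linear, log2 was taken; the design fixed before the data were examined had allowed for this. No value was filtered out and no pseudocount was added. The design of the tests, the rule for named genes, the gene lists and most of the other settings listed at the end were also set before the data were examined.

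Gene names came from the platform's annotation table. It lists 28898 probe sets with 1 gene symbol, 551 with several and 15692 with none, of which 104 are controls; 28689 of the Entrez identifiers of the first kind were found in the RefSeq table of assembly GRCm38.p6, which served for current symbols and for the order of genes along chromosomes. Probe sets with several symbols name no gene here. Each of the 17097 genes was tested through the probe set with the highest mean over the arrays of the fit. No genome sequence or probe sequence was used here, so no coordinates are given, and whether a strain's sequence differs under a probe was not analysed here. The background of an array was the 95th percentile of its 23 non-specific control probe sets. Where the mean of a group lay at or under that of its arrays' backgrounds, the log2 difference is as measured and the fold is given only as a bound, the brighter group's mean against the mean of, per array, the higher of background and value. In the mean of the 3 time points the dimmer strain's groups at background were treated likewise, and no size is given where a group of the brighter strain lay there as well.

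Groups were formed from the strain and the time given in the labels. The labels call 2 of the 4 arrays of C57BL/6 at 24 h technical without stating which RNA they repeat, so these 2 entered only alternatives. The numbers given to replicates were not taken as pairing samples. The labels do not say that samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical. No 2 arrays held identical values.

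Differential expression was tested with limma 3.58.1 in R 4.3.3. All 26 biological arrays entered 1 fit with a mean for each of the 9 groups, so that they shared 1 estimate of the spread, followed by contrasts and eBayes. Adjusted p-values are Benjamini-Hochberg values over all genes of a contrast, and genes under 0.05 were called. There were 22 contrasts, namely the 3 strain pairs at each time and over the mean of the 3 time points, 4 h and 24 h against unstimulated in each strain, and 4 differences between responses. For each strain contrast the rule named Slamf6 and the other SLAM family members, the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the groups (for the mean, whose group means differed in the same direction at all 3 times), and up to 4 members of each list with the smallest adjusted p. Activation contrasts followed the same rule, and each interaction up to 10 genes in each direction. The text leaves some out, taking the largest first.

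The 27 gene lists covered the SLAM family and adaptors, Sle1b region neighbours on chromosome 1, immediate early and TCR-induced regulators, activation surface markers, T cell cytokines and chemokines, naive and quiescence genes, cell cycle, ribosome biogenesis, glycolysis, cholesterol synthesis, an amino acid and one-carbon stress response, the type I interferon response, the interferon gamma response, T follicular helper genes, regulatory T cell genes, memory and effector genes, TCR signalling, apoptosis and heat shock. Markers of B cells, plasma cells, monocytes and macrophages, neutrophils, dendritic cells, NK cells, CD8 T cells and erythroid cells made up the rest. Each was tested with camera at its preset correlation of 0.01, again with a correlation estimated from the residuals, and with fry, and adjusted over the 27 lists. The text gives the camera results, with fry added for 1 list only. Camera compares the members of a list with all other genes, whereas fry tests whether the members move in 1 direction on balance, without reference to other genes. Clustering near Slamf6 was tested with Fisher's exact test, two-sided. Comparisons that share arrays were set beside 50 simulations without a strain effect and 50 without an effect of the added chromosome, made by shuffling the arrays' residuals. After their results had been seen, the genes with the smallest p in each simulation, as many as were called here, were compared as well. Correlations across arrays had 100000 permutations.

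The steps were tested on simulated data, with 200 of the 17097 genes changed by known folds in 20 draws per contrast. For B6.Sle1b against C57BL/6 unstimulated, 32.8%, 79.1% and 99.2% of the genes changed 1.5-fold, 2-fold and 4-fold were found; over the 3 time points these shares were 77.6%, 98.5% and 100%, and at 24 h 23.9%, 67.2% and 97.0%. They were 31.3%, 76.9% and 100% for Sle1b.BAC against B6.Sle1b unstimulated, 23.9%, 68.7% and 98.5% for C57BL/6 at 24 h against unstimulated, and 12.7%, 50.0% and 92.4% for the 24 h response of Sle1b.BAC against B6.Sle1b. The median number of false calls was 0 to 1, but single draws gave up to 622 in the first of these contrasts. With the preset correlation, camera found the 1 shifted list in 17 to 20 of 20 draws and called a median of 5 to 7 others with it. With the estimated correlation it found the list in 9 to 17 draws, at a median of 0 others. List results are therefore led by the calls that hold with an estimated correlation.

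Other settings set in advance were all 28 arrays, the technical pair averaged as 1 array, replicate number as a block, strain and replicate number as a random block, trend and robust eBayes, array weights, only the groups compared, dim genes left out, the mean of a gene's probe sets, every probe set, quantile normalizing again, centring on the median, 100 tested genes on either side of Slamf6, an adjusted p under 0.01 for the reversal, and leaving out each array in turn. For the genes that reversed, most of these were added after seeing the data. A further 6 were added then, namely the SLAM family list without Slamf6 and with Slamf6 as the mean of its probe sets, array brightness (the 75th percentile) as covariate, the 3 dim arrays left out, the technical arrays merged with their nearest biological array, and array weights computed gene by gene. The last was added because the iterations behind limma's default array weights stopped before they converged. Gene-by-gene weights depend in turn on the order of the genes, so their counts were also taken over 20 shuffled orders.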

Results

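Messenger RNA was measured on whole-transcriptome arrays in total CD4+ T cells from the spleens of 12-week-old female mice of 3 strains. C57BL/6 was the reference. B6.Sle1b carries on that background an interval of chromosome 1 that is linked to lupus susceptibility and spans the SLAM receptor family, lymphocyte surface proteins that include Slamf6 (Ly108). The third strain, Sle1b.BACSlamf6-H1, written Sle1b.BAC here, is B6.Sle1b with a bacterial artificial chromosome named for the H1 splice form of Slamf6. Cells were unstimulated or had been on plate-bound antibody to CD3, which triggers the T cell receptor, at 0.1 µg/ml for 4 h or 24 h. Of the 28 arrays, 26 were labelled biological and entered the comparisons. They made up 8 groups of 3 and, for C57BL/6 at 24 h, 1 group of 2, beside 2 further arrays labelled technical.

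The median intensity of an array lay between 9.06 and 10.5 and its 75th percentile between 34.2 and 53.3. Non-specific control probe sets put the background at a log2 intensity of 2.76 to 3.21. A total of 17097 genes were tested, each through 1 probe set, and the number of arrays limits the precision. Within groups, 66.0% of the variance of the 5157 genes with a mean log2 above 6 lay along 1 axis. The position of the 26 arrays on that axis followed their 75th percentile (Pearson r = -0.864, Spearman rho = -0.839, permutation p = 1e-05, the smallest possible, and 2e-05; adjusted p = 2.5e-05 over 5 array measures). Without the 2 arrays farthest from the median, r was -0.807. The hybridisation spikes followed the axis as well (r = 0.779, adjusted p = 2.5e-05, and 0.786 without the 2 arrays farthest from their own median). So did 18S ribosomal RNA (r = 0.641, adjusted p = 8.17e-04, Spearman rho = 0.333, and r = 0.405 without its own 2 farthest arrays). Whether either follows the axis apart from brightness was not tested. Outside the 24 h groups the dimmest arrays were array 2 of unstimulated C57BL/6 (34.8), array 3 of unstimulated B6.Sle1b (35.6) and array 2 of Sle1b.BAC at 4 h (34.2). Differences are given as log2 ± standard error (SE), and a gene is called where its adjusted p was under 0.05. Where the dimmer group lay at background, "at least N-fold" is the brighter group's mean over that background.

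Slamf6, the gene the third strain was built around, was the first item to compare. It is read by 3 probe sets on the array, and these moved apart. The brightest, which stands for the gene in all counts, was higher in both congenic lines. In unstimulated cells its log2 intensity was 7.28 in C57BL/6, 8.40 in B6.Sle1b and 8.49 in Sle1b.BAC (n = 3 each). Over the 3 time points it was 2.59-fold higher in B6.Sle1b than in C57BL/6 (log2 1.38 ± 0.10, adjusted p = 4.82e-08). The other two probe sets were lower in B6.Sle1b, the brighter by log2 -1.74 ± 0.12 (adjusted p = 5.89e-08 over all probe sets) and the dimmer by an amount that was not measured exactly (adjusted p = 8.58e-13). The latter measured log2 3.73, 5.20 and 4.07 in C57BL/6 unstimulated, at 4 h and at 24 h, and lay at background in both congenic lines at every time, so neither the size of the difference nor a response in those lines can be given. In C57BL/6 it rose by 1.47 ± 0.12 at 4 h (adjusted p = 6.39e-08 over all probe sets). Between Sle1b.BAC and B6.Sle1b the 2 brighter probe sets differed by 0.06 ± 0.10 and 0.34 ± 0.12, and neither was called (adjusted p = 0.923 and 0.473). The second was higher in Sle1b.BAC at each time (0.25, 0.46 and 0.30). Its 95% confidence interval over the 3 times, not adjusted over probe sets, was 0.09 to 0.58, so a small rise is not excluded. The direction given for Slamf6 as a gene therefore holds for the brightest probe set; averaged over its probe sets, the one at background included, Slamf6 was lower in B6.Sle1b than in C57BL/6, by log2 -0.77 over the 3 time points.

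**Figure D1:**
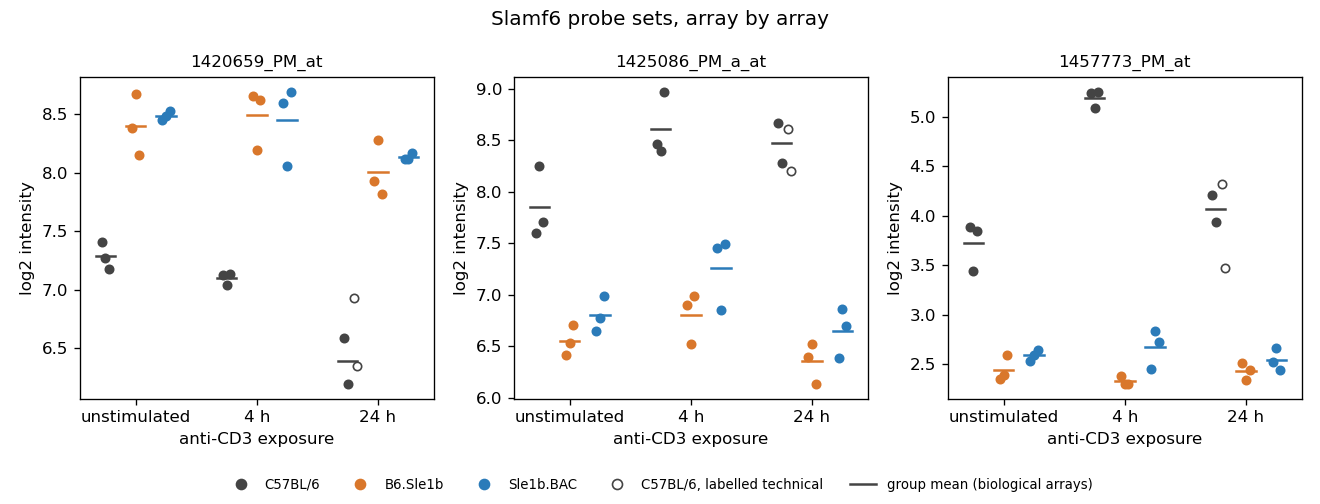
Log2 intensity of the 3 Slamf6 probe sets (y axis) on each array, by strain and hours on anti-CD3 (x axis), with points for biological arrays, open circles for arrays labelled technical and lines for the means of biological arrays. The brightest is higher in both congenic lines (8.40 and 8.49 against 7.28 unstimulated), and the other 2 probe sets are lower.

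The comparison of B6.Sle1b with C57BL/6 asked what the interval does to CD4+ T cells at each time. In unstimulated cells, 21 genes were called, 18 higher and 3 lower in B6.Sle1b. Among the highest were the antiviral interferon-induced gene Rsad2 (2.20 ± 0.42, adjusted p = 0.0332), the secreted BMP and Wnt antagonist Sostdc1 (2.00 ± 0.24, adjusted p = 2.02e-04) and the cysteine protease inhibitor Stfa3 (2.18 ± 0.26, at least 2.94-fold). The peptidylarginine deiminase Padi4 (1.21 ± 0.17, at least 1.58-fold), the calcium-dependent kinase gene Camk2b (1.15 ± 0.16) and Slamf6 (1.12 ± 0.17, adjusted p = 0.00298) were also higher. So were 1810009J06Rik (1.39 ± 0.21), the pseudogene Pisd-ps3 (1.56 ± 0.29), the itaconate-producing enzyme Acod1 (1.45 ± 0.27) and the pro-apoptotic gene Pmaip1 (1.26 ± 0.25). The antiviral GTPase Mx1 was higher by 0.81 ± 0.15 (at least 1.68-fold) and the surface glycoprotein Cd200 by 0.66 ± 0.13. Rell1, of the RELT receptor family, was lower by -1.76 ± 0.16 (adjusted p = 5.93e-06), the calcium-binding gene Efhd2 by -1.21 ± 0.16 and 1810046K07Rik by -0.95 ± 0.15 (at least 1.59-fold). At an unadjusted p under 0.05 there were 707 genes, where 855 are expected by chance. With only the groups compared none of the 21 was called. The count was 12 without array 2 and 11 without array 3 of C57BL/6. It was 34 with quantile normalizing again, 55 with brightness as covariate and 135 with gene-by-gene weights. Stfa3, Sostdc1, 1810009J06Rik, Padi4, Camk2b, Slamf6, Rell1 and Efhd2 kept their calls without each array in turn, whereas Rsad2, Pisd-ps3, Acod1, Pmaip1, Mx1, Cd200 and 1810046K07Rik lost them without at least 1 (adjusted p up to 0.335, for Cd200 and Pmaip1 without array 2 of C57BL/6).

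After 4 h of anti-CD3, 7 genes were called. Pisd-ps3 (1.73 ± 0.29) and Slamf6 (1.39 ± 0.17, adjusted p = 7.31e-04) were higher in B6.Sle1b. The lipoprotein gene Apoe (-1.62 ± 0.27), Rell1 (-1.23 ± 0.16), Efhd2 (-0.94 ± 0.16), the mitochondrial iron importer Slc25a37 (-0.90 ± 0.13) and H2-Oa, a chain of the class II regulator H2-O (-0.85 ± 0.12), were lower. After 24 h, 7 genes were called again, with 2 C57BL/6 arrays. Pisd-ps3 (1.89 ± 0.33), Slamf6 (1.62 ± 0.19, adjusted p = 3.64e-04), the protein C receptor Procr (1.22 ± 0.22, at least 2.22-fold) and Efcab7 (0.99 ± 0.17) were higher. Rell1 (-1.12 ± 0.18), H2-Oa (-0.85 ± 0.13) and Slc25a37 (-0.84 ± 0.15) were lower. Unadjusted p under 0.05 held for 617 genes at 4 h and 805 at 24 h. The 4 h count was 4 without array 2 of C57BL/6 or array 3 of B6.Sle1b. The 24 h count was 1 without array 1 of C57BL/6, where Slamf6 stayed called, and 2 without array 1, 2 or 3 of B6.Sle1b. Apoe, Efhd2 and Pisd-ps3 at 4 h, and at 24 h every called gene except Slamf6, lost their calls without at least 1 array (adjusted p up to 0.267 at 4 h, for Efhd2 without array 3 of B6.Sle1b, and 0.79 at 24 h, for Rell1 and H2-Oa without array 1 of C57BL/6). Quantile normalizing the values again called 5 higher and 6 lower genes at 4 h, and 5 and 0 at 24 h. Centring each array on its median called 1 higher and 2 lower at 24 h. With only the groups compared 2 genes were called at 4 h and 0 at 24 h. With all 28 arrays, the technical ones included, 12 higher and 33 lower genes were called at 24 h, and with the technical pair averaged as 1 array 6 and 7.

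Averaged over the 3 time points, 57 genes were called between B6.Sle1b and C57BL/6, 31 higher and 26 lower, and 873 had an unadjusted p under 0.05. Besides Slamf6 and Pisd-ps3 (1.73 ± 0.18), the highest were the protease inhibitor Slpi (1.74 ± 0.27), the immunoglobulin segment Igk-V21 (1.60 ± 0.35), the myeloid lysozyme Lyz2 (1.28 ± 0.22), the interleukin 1 decoy receptor Il1r2 (1.08 ± 0.21), Gpm6b (1.07 ± 0.20) and Sostdc1 (1.0 ± 0.14). Stfa3 was called higher as well (adjusted p = 0.0018), but lay above background in unstimulated B6.Sle1b alone, so no size is given over the 3 time points. Il17a, the cytokine of Th17 cells, was higher by 0.98 ± 0.17 (adjusted p = 0.00865). Rell1 (-1.37 ± 0.10, adjusted p = 4.78e-08), Efhd2 (-1.03 ± 0.10), Apoe (-1.02 ± 0.16), Slc25a37 (-0.79 ± 0.08), the peptide hormone Adm (-0.79 ± 0.14), Dnajc16 (-0.77 ± 0.11) and the receptor Gpr34 (-0.84 ± 0.17, at least 1.49-fold) were lower. The B cell genes Cd79b (-0.89 ± 0.14), Ms4a1 (-0.88 ± 0.19) and H2-Eb1 (-0.68 ± 0.14) were lower too. Without array 1 of C57BL/6 at 24 h the count was 27. With strain and replicate number as a random block it was 33, and with only the groups compared 30. It was 118 with brightness as covariate, 267 with array weights and 117 with gene-by-gene weights. Adm, Gpm6b, Gpr34, H2-Eb1, Igk-V21, Il1r2 and Ms4a1 lost their calls without at least 1 array (adjusted p up to 0.328, for Igk-V21 without array 1 of C57BL/6 at 24 h).

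Of the 27 gene lists fixed in advance, some moved together between B6.Sle1b and C57BL/6 in unstimulated cells. The type I interferon response was higher, with 2 of 17 members called (Rsad2 and Mx1, also 2 adjusted over the list alone), none lower, and 15 not called. All 17 were above 0, with a median of 0.81 (camera adjusted p = 1.58e-15; adjusted p = 0.0498 with an estimated correlation). The interferon gamma response was higher with 0 of 14 called and 5 adjusted over the list alone. Of its members, the guanylate-binding protein Gbp2 measured 0.71 ± 0.16 (adjusted p = 0.111) and the chemokine Cxcl10 1.5 ± 0.46 (adjusted p = 2.17e-10 for the list; adjusted p = 0.0267 with an estimated correlation). T follicular helper genes were higher with 2 of 15 called, Cd200 and Sostdc1, and 2 adjusted over the list alone (adjusted p = 7.59e-09; adjusted p = 0.00687 with an estimated correlation). Activation surface markers were higher with 0 of 15 called and 2 adjusted over the list alone, the checkpoint receptor Lag3 (1.19 ± 0.26) and the transferrin receptor Tfrc (0.59 ± 0.18; adjusted p = 2.73e-06 and adjusted p = 0.0433 with an estimated correlation). Heat shock genes were higher with 0 of 8 called and 2 adjusted over the list alone, among them Hspa1b at 1.03 ± 0.29 (adjusted p = 6.49e-04; adjusted p = 0.0182 with an estimated correlation). Their shift was not called without the 3 dim arrays (adjusted p = 0.117). B cell markers were lower with 0 of 14 called and 1 adjusted over the list alone, Cd79b (adjusted p = 4.78e-06; adjusted p = 0.0498 with an estimated correlation). Neutrophil markers moved the other way on the same arrays, with a mean log2 of 4.00 ± 0.64 (SD) in C57BL/6 and 5.19 ± 1.05 in B6.Sle1b (adjusted p = 1.23e-04; adjusted p = 0.149 with an estimated correlation). The cell cycle list was higher with 0 of 29 called (adjusted p = 2.64e-08; adjusted p = 0.24 with an estimated correlation).

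At 4 h the T follicular helper list was again higher in B6.Sle1b with 0 of 15 called (adjusted p = 5.85e-06; adjusted p = 0.0492 with an estimated correlation). The type I interferon list was higher with 0 of 17 called and 2 adjusted over the list alone, Mx1 and Rsad2 (adjusted p = 8.53e-07; adjusted p = 0.28 with an estimated correlation). B cell markers were lower with 0 of 14 called and 6 adjusted over the list alone (adjusted p = 7.6e-07; adjusted p = 0.0576 with an estimated correlation). At 24 h, 5 lists shifted and none of them with an estimated correlation, where adjusted p was 0.575 for the SLAM family and 0.805 for the other four.

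Over the 3 time points 2 of 9 SLAM family members were called higher in B6.Sle1b, Slamf6 and the adhesion receptor Cd84 (0.53 ± 0.11, adjusted p = 0.0458), and 3 adjusted over the list alone (adjusted p = 5.24e-04; adjusted p = 0.043 with an estimated correlation). That list result rested on the brightest probe set of Slamf6. With an estimated correlation it was not called without Slamf6 (adjusted p = 0.498), nor with Slamf6 as the mean of its probe sets, where the direction turned (adjusted p = 0.756). Slamf1 measured 0.31 ± 0.11 and Ly9 -0.17 ± 0.14, and neither was called. Activation surface markers were higher with 2 of 15 called, Lag3 (0.72 ± 0.16) and the inhibitory receptor Ctla4 (0.39 ± 0.09), and 7 adjusted over the list alone (adjusted p = 2e-08; adjusted p = 0.0147 with an estimated correlation). T follicular helper genes had 1 of 15 called and 5 adjusted over the list alone (adjusted p = 9.13e-07; adjusted p = 0.0147 with an estimated correlation), and heat shock genes 0 of 8 and 2 (adjusted p = 4.58e-04; adjusted p = 0.0147 with an estimated correlation). B cell markers were lower with 3 of 14 called, Cd79b, Ms4a1 and the class II gene H2-Aa (-0.67 ± 0.14), and 5 lower and 1 higher adjusted over the list alone (adjusted p = 4.46e-07; adjusted p = 0.035 with an estimated correlation). Neutrophil markers were higher with 0 of 7 called, 2 adjusted over the list alone and a median of 0.88 (adjusted p = 3.65e-08; adjusted p = 0.0372 with an estimated correlation). Mx1 (0.60 ± 0.09, at least 1.47-fold, adjusted p = 0.00143) and Rsad2 (1.2 ± 0.25) were called, while the type I interferon list as a whole had adjusted p = 8.11e-09 and adjusted p = 0.14 with an estimated correlation. Cd84, Lag3, Ctla4, H2-Aa and Rsad2 lost their calls without at least 1 array (adjusted p up to 0.217, for Ctla4 without array 1 of C57BL/6 at 24 h).

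Whether the differences clustered around Slamf6 was asked next. Of the 50 genes tested nearest to Slamf6 on chromosome 1, 25 on each side, 3 were called over the 3 time points, against 52 of 16885 others (Fisher's exact test, two-sided p = 5.7e-04, adjusted p = 0.00684 over 12 comparisons). The 3 were Cd84, the mitochondrial import gene Tomm40l (-0.58 ± 0.10, adjusted p = 0.00957) and Gm20045, which was named after its values were seen. Whether the strains' sequences differ under the probes of these genes was not analysed here, so a difference in binding is not excluded. With 100 genes on each side the exact p was 0.0272 (adjusted p = 0.326). For Sle1b.BAC against C57BL/6, 1 of 50, Tomm40l, was called against 36 of 16885 (exact p = 0.104, adjusted p = 0.622), and that exact p was 0.00104 with array brightness as covariate and 1.75e-04 without the 3 dim arrays. Cd84 and Tomm40l lost their calls without array 1 of C57BL/6 at 24 h (adjusted p = 0.162 and 0.0676).

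The comparison of Sle1b.BAC with B6.Sle1b asked what the added chromosome changes within the congenic background. In unstimulated cells 14 genes were called, all 14 lower in Sle1b.BAC. Stfa3 was lower by -2.57 ± 0.26 (adjusted p = 3.69e-05, at least 3.48-fold), Sostdc1 by -1.71 ± 0.24 (adjusted p = 0.0024), 1810009J06Rik by -1.64 ± 0.21 (adjusted p = 0.00104) and the relaxin-family hormone Insl6 by -1.21 ± 0.20. Padi4 (-1.15 ± 0.17, at least 1.87-fold), the protease inhibitor Cst7 (-1.02 ± 0.15), Ms4a6d (-1.14 ± 0.19), Nrn1 (-0.98 ± 0.18), the inflammatory caspase Casp1 (-0.92 ± 0.18), Mx1 (-0.83 ± 0.15) and the folate receptor family gene Izumo1r (-0.66 ± 0.13) were lower as well. At an unadjusted p under 0.05 there were 1390 genes. Quantile normalizing the values again called 4 higher and 14 lower, and with only the groups compared none of the 14 was called. The count was 9 without array 1 and 32 without array 2 of B6.Sle1b, and 6, 6 and 5 without arrays 1, 2 and 3 of Sle1b.BAC. Stfa3, Sostdc1, 1810009J06Rik, Padi4 and Cst7 kept their calls without each array, and the other six named lost theirs without at least 1 (adjusted p up to 0.289, for Casp1 without array 2 of Sle1b.BAC).

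T follicular helper genes were lower in unstimulated Sle1b.BAC than in B6.Sle1b, with 2 of 15 called, Sostdc1 and Izumo1r, and 7 lower and 1 higher adjusted over the list alone (adjusted p = 3.68e-06; adjusted p = 0.0389 with an estimated correlation). Of their members, Cd200 measured -0.59 ± 0.13 and Il6ra, the interleukin 6 receptor, 0.81 ± 0.19. The type I interferon list was lower with Mx1 called of 17 and 6 adjusted over the list alone (adjusted p = 1.6e-06; adjusted p = 0.401 with an estimated correlation). The interferon gamma list was lower with 0 of 14 called and 3 adjusted over the list alone (adjusted p = 8.12e-06; adjusted p = 0.209 with an estimated correlation). Naive and quiescence genes were higher with 0 of 13 called and 2 adjusted over the list alone, the transcription factor Bach2 (0.97 ± 0.25) and the egress receptor S1pr1 (0.58 ± 0.18; adjusted p = 1.01e-06 and adjusted p = 0.248 with an estimated correlation). Neutrophil markers were not lower on these arrays, at a mean log2 of 5.56 ± 0.90 (SD) in Sle1b.BAC and 5.19 ± 1.05 in B6.Sle1b.

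At 4 h and at 24 h limma called 0 genes between Sle1b.BAC and B6.Sle1b, with 613 and 908 at an unadjusted p under 0.05; without array 2 of Sle1b.BAC, 3 genes were called at 24 h. At 4 h, 10 lists shifted and none with an estimated correlation (adjusted p = 0.289 or more), and at 24 h no list shifted. Over the 3 time points 14 genes were called, 3 higher and 11 lower, with 1041 at an unadjusted p under 0.05. The mitochondrial tRNA-modifying gene Cdk5rap1 (0.83 ± 0.15), the mRNA export gene Thoc2 (0.53 ± 0.09) and the calcium pump Atp2b1 (0.49 ± 0.09) were higher. Gpm6b (-1.03 ± 0.19), Sostdc1 (-1.0 ± 0.14, at least 1.94-fold), 1810009J06Rik (-0.90 ± 0.12), Cc2d2a (-0.52 ± 0.10, at least 1.38-fold), Cst7 (-0.48 ± 0.08), Sdcbp2 (-0.46 ± 0.08), Mx1 (-0.46 ± 0.08), Ankrd37 (-0.43 ± 0.08) and Izumo1r (-0.40 ± 0.07) were lower. Stfa3 and Padi4 were lower too (adjusted p = 0.00197 and 0.00634), but no size is given for them, since of these groups Stfa3 lay above background in unstimulated B6.Sle1b alone and Padi4 in B6.Sle1b unstimulated and at 4 h alone. Quantile normalizing again called 10 higher and 14 lower, and centring on the median 2 and 4. Without the 3 dim arrays 27 higher and 14 lower were called. With strain and replicate number as a random block 3 of the 14 remained called, namely Stfa3, Sostdc1 and 1810009J06Rik. Only Stfa3, Sostdc1, 1810009J06Rik and Padi4 of these 14 kept their calls without each array in turn, and adjusted p reached 0.148 among the others, for Cc2d2a without array 2 of unstimulated Sle1b.BAC. The count was 4 without array 2 of unstimulated Sle1b.BAC and lay between 6 and 9 without any one of 12 other arrays, namely array 3 of unstimulated B6.Sle1b, array 1 of unstimulated Sle1b.BAC, the 3 B6.Sle1b arrays at 4 h, arrays 1 and 3 of Sle1b.BAC at 4 h, arrays 1 and 2 of B6.Sle1b at 24 h and the 3 Sle1b.BAC arrays at 24 h.

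Genes that were higher in B6.Sle1b than in C57BL/6 and lower in Sle1b.BAC than in B6.Sle1b were counted next. In unstimulated cells there were 6, namely Stfa3, Sostdc1, 1810009J06Rik, Padi4, Insl6 and Mx1. Over the 3 time points there were 7, namely Stfa3, Sostdc1, Padi4, Mx1, Gpm6b, Cc2d2a and Sdcbp2, and 0 moved the other way. The latter count was 2 with strain and replicate number as a random block (Stfa3 and Sostdc1), 3 with only the groups compared or with centring on the median, 25 with brightness as covariate and 3 to 8 without each array in turn, where only Stfa3, Sostdc1 and Padi4 stayed throughout. The unstimulated count was 0 with only the groups compared, 23 with brightness as covariate and 4 to 9 without each array, where Stfa3, Sostdc1, 1810009J06Rik and Padi4 stayed throughout. Both comparisons share the B6.Sle1b arrays, which pushes them apart with no effect at all. Independent lists would share 0.0199. In 50 simulations without an effect of the added chromosome, Sle1b.BAC against B6.Sle1b had 0 calls, so calls cannot be compared there. Taking instead the 57 and 14 genes with the smallest p in each simulation, 0 to 4 were in both with opposite signs (median 0), and 0 to 2 for the 21 and 14 in unstimulated cells. In 50 simulations without any strain effect these ranges were 0 to 12 (as many as 7 in 1 of 50) and 0 to 5. With the B6.Sle1b arrays split so that each comparison had its own, the median over 54 splits was 0 genes and the range 0 to 6. Across the 57 genes called between B6.Sle1b and C57BL/6, 77.2% had the opposite sign in Sle1b.BAC against B6.Sle1b, where the simulations without an effect of the added chromosome gave a median of 71.0% and 17 of 50 gave as much. Across all genes, which are not independent replicates, the covariance of the log2 differences was -0.0066. The median was -0.0059 in the simulations without an effect of the added chromosome (19 of 50 as far below 0) and -0.0051 in those without any strain effect (23 of 50).

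**Figure D2:**
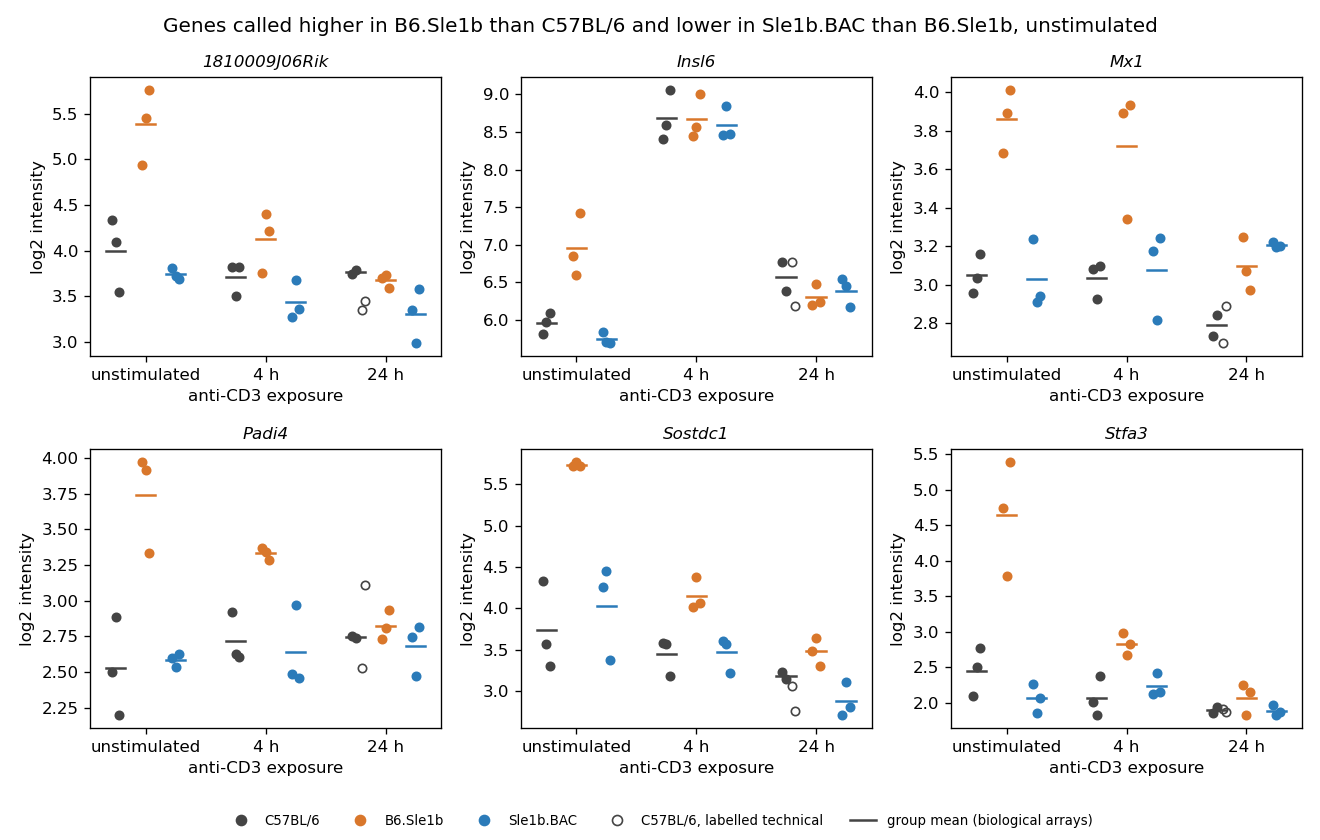
Log2 intensity (y axis) of the 6 genes called both higher in unstimulated B6.Sle1b than in C57BL/6 and lower in unstimulated Sle1b.BAC than in B6.Sle1b, on each array, by strain and hours on anti-CD3 (x axis), with points for biological arrays, open circles for arrays labelled technical and lines for the means of biological arrays. In unstimulated cells Sostdc1 is 2.00 higher in B6.Sle1b than in C57BL/6 and 1.71 lower again in Sle1b.BAC.

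Sle1b.BAC was also compared with C57BL/6. In unstimulated cells 10 genes were called. Only the groups compared gave 1, brightness as covariate 22 and gene-by-gene weights 31. Pisd-ps3 (2.20 ± 0.29), Cdk5rap1 (1.59 ± 0.26), Slamf6 (1.2 ± 0.17, adjusted p = 0.00117), Enc1 (1.2 ± 0.17) and the lubricin gene Prg4 (0.98 ± 0.17) were higher. Rell1 (-1.66 ± 0.16, adjusted p = 1.76e-05), Efhd2 (-1.31 ± 0.16), Synj2 (-0.94 ± 0.13), H2-Oa (-0.87 ± 0.12) and the DNA repair gene Mgmt (-0.78 ± 0.13) were lower. At 4 h, 11 genes were called, 6 higher, among them the RNA-binding regulator Rc3h2 (1.16 ± 0.20), Arhgap5 (0.90 ± 0.15) and Thoc2 (0.87 ± 0.15), and 5 lower, among them the B cell scaffold Bank1 (-1.27 ± 0.21) and Ddt (-0.68 ± 0.13). At 24 h, 6 genes were called, with Il17a (2.04 ± 0.32, adjusted p = 0.0122), Efcab7 (1.36 ± 0.17) and BC062258 (0.89 ± 0.15) higher beside Pisd-ps3 and Slamf6, and Slc25a37 lower (-0.90 ± 0.15). Unadjusted p under 0.05 held for 968, 987 and 392 genes. At 4 h, quantile normalizing again called 18 higher and 24 lower, leaving out the 3 dim arrays 19 and 4, brightness as covariate 49 and 161, and only the groups compared 0, and at 24 h centring on the median called 4 and 0 and all 28 arrays 7 and 4. The 4 h count was 5 and 3 without arrays 1 and 2 of C57BL/6, 19 without array 3, and 6 and 5 without arrays 1 and 3 of Sle1b.BAC. The 24 h count was 3 and 1 without arrays 1 and 2 of C57BL/6 and 3 without array 3 of Sle1b.BAC. Cdk5rap1, Mgmt and Prg4 in unstimulated cells, every gene except Efhd2, Rell1 and Slamf6 at 4 h, and every gene except Slamf6 at 24 h lost their calls without at least 1 array (adjusted p up to 0.331 for Prg4 without array 1 of Sle1b.BAC, 0.411 for Ddt without array 2 of C57BL/6 and 0.529 for BC062258 and Slc25a37 without array 2 of C57BL/6).

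Over the 3 time points 39 genes were called between Sle1b.BAC and C57BL/6, 15 higher and 24 lower, with 1172 at an unadjusted p under 0.05. Il17a (1.2 ± 0.17, adjusted p = 0.0016), Cdk5rap1 (1.45 ± 0.16), Lyz2 (1.47 ± 0.22), the neutrophil calprotectin gene S100a8 (3.32 ± 0.69, adjusted p = 0.0398) and the mitochondrial transhydrogenase Nnt (0.78 ± 0.12) were higher. H2-Oa (-0.74 ± 0.07), Bank1 (-0.83 ± 0.12), Apoe (-0.86 ± 0.16), Slc25a37 (-0.70 ± 0.08) and Tomm40l (-0.66 ± 0.10) were lower. B cell markers were lower with 3 of 14 called, Bank1, H2-Aa and Cd79b, and 9 adjusted over the list alone (adjusted p = 5.37e-10; adjusted p = 0.0261 with an estimated correlation). Neutrophil markers were higher with S100a8 called of 7 and 4 adjusted over the list alone (adjusted p = 8.3e-09; adjusted p = 0.044 with an estimated correlation). With fry their adjusted p was 0.0625, so that test did not call the shift. Of the 9 SLAM family members Slamf6 was called, and 2 higher and 1 lower adjusted over the list alone (adjusted p = 2.21e-04; adjusted p = 0.044 with an estimated correlation). This list result again rested on the brightest probe set of Slamf6, with adjusted p = 0.679 without Slamf6 and 0.86 with the mean of its probe sets, both with an estimated correlation. Without array 1 of C57BL/6 at 24 h the count was 21, and with all 28 arrays 23 higher and 42 lower were called. With strain and replicate number as a random block the count was 24, and with brightness as covariate 154. S100a8, Apoe, Cd79b, Dnajc16 and H2-Aa lost their calls without at least 1 array (adjusted p up to 0.22, for Cd79b without array 1 of C57BL/6 at 24 h).

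Both congenic lines differed from C57BL/6 at 24 genes in the same direction, 11 higher and 13 lower. Rell1, Efhd2, Apoe, Slc25a37, H2-Oa, H2-Aa, Cd79b, Dnajc16 and Tomm40l were among the lower ones, and Slamf6, Pisd-ps3, Il17a, Lyz2, Nnt and Camk2b among the higher ones. Independent lists would share 0.0272 higher and 0.0365 lower genes. Simulations with no strain effect called at most 1 gene between Sle1b.BAC and C57BL/6, so calls cannot be compared there; of the 57 and 39 genes with the smallest p in each, 0 to 13 were in both with the same sign (median 5). With the C57BL/6 arrays split so that each line had its own, the median over 36 splits was 7 shared genes and the range 6 to 10. The covariance of the log2 differences across all genes was 0.00968, against a median of 0.00747 in the simulations with no strain effect (range -0.0032 to 0.0412). Of these, 21 of 50 gave as much.

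**Figure D3:**
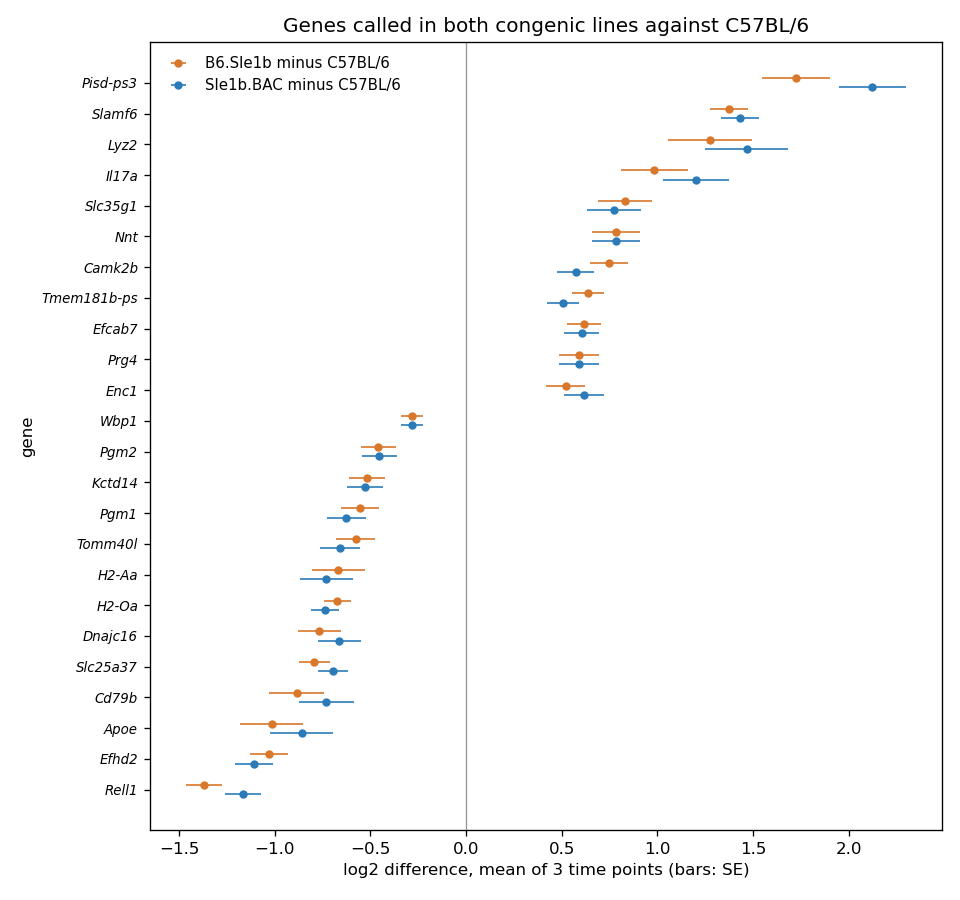
Log2 difference from C57BL/6, averaged over the 3 time points (x axis, bars are SE), of the 24 genes called in the same direction in both congenic lines (y axis), for B6.Sle1b and Sle1b.BAC. Rell1 lies at -1.37 and -1.17 and Slamf6 at 1.38 and 1.43.

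Activation through CD3 was compared with the unstimulated state within each strain. The labels give unstimulated cells no time in culture, and no group was cultured for 4 h or 24 h without the antibody. These comparisons therefore do not separate the antibody from time in culture. At 4 h, 1204 genes changed in C57BL/6 (697 higher, 507 lower), 973 in B6.Sle1b (440 and 533) and 1808 in Sle1b.BAC (722 and 1086), of which 429, 358 and 633 changed at least 2-fold. Without the 3 dim arrays 1083 were higher and 1317 lower in C57BL/6, and 605 and 1406 in B6.Sle1b. With only the groups compared C57BL/6 had 474 in all, and B6.Sle1b had 185 higher and 166 lower. The chemokine Ccl3 rose most in C57BL/6 (5.60 ± 0.41, at least 41.5-fold) and rose by 5.0 ± 0.41 and 5.01 ± 0.41 in the congenic lines. Cytokine and chemokine genes rose together, with 11, 9 and 12 of 19 called higher in C57BL/6, B6.Sle1b and Sle1b.BAC, 0, 1 and 1 lower, and 13, 12 and 13 higher adjusted over the list alone. Csf2 rose by 4.30 ± 0.30, 3.20 ± 0.30 and 3.13 ± 0.30, and Il4 by 3.92 ± 0.27, 3.21 ± 0.27 and 3.80 ± 0.27 (list adjusted p = 2.1e-16, 1.56e-15 and 9.56e-14; adjusted p = 0.0226, 0.0283 and 0.0457 with an estimated correlation). The interferon gamma response rose with 11, 9 and 11 of 14 called and 12, 11 and 11 adjusted over the list alone. Its member Gbp2 rose by 3.56 ± 0.16, 2.73 ± 0.16 and 3.48 ± 0.16, and the suppressor Socs1 rose by 3.86 ± 0.25 in C57BL/6 (list adjusted p = 1.43e-27, 1.8e-19 and 9.17e-18; adjusted p = 6.34e-04, 0.00428 and 0.00681 with an estimated correlation). The type I interferon response had 11, 9 and 11 of 17 called higher and 11 in each strain adjusted over the list alone, with Usp18 at 3.56 ± 0.34, 2.99 ± 0.34 and 3.22 ± 0.34 (list adjusted p = 5.73e-14, 6.77e-11 and 5.03e-09; adjusted p = 0.135, 0.174 and 0.344 with an estimated correlation).

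Immediate early and TCR-induced regulators had 4 of 21 called higher and 3 lower in each strain at 4 h, with 6, 5 and 4 higher and 4, 3 and 4 lower adjusted over the list alone (list adjusted p = 0.242, 0.00944 and 0.441; adjusted p = 0.946, 0.732 and 0.909 with an estimated correlation). Of single genes in C57BL/6, Egr1 (3.10 ± 0.36), Myc (2.30 ± 0.25), Irf4 (2.10 ± 0.22), the interleukin 2 receptor Il2ra (2.42 ± 0.26), the Th1 regulator Tbx21 (2.35 ± 0.44) and the early activation antigen Cd69 (1.08 ± 0.23) rose, while Fosb (-1.89 ± 0.36) and Ctla4 (-0.72 ± 0.14) fell. The death receptor Fas (1.71 ± 0.16) and the survival gene Bcl2 (1.68 ± 0.20) rose, with 6 of 15 apoptosis genes called higher and 7 higher and 2 lower adjusted over the list alone (list adjusted p = 1.64e-04; adjusted p = 0.135 with an estimated correlation). Naive and quiescence genes fell, with 5 of 13 called lower and 1 higher in C57BL/6, and 7 and 1 adjusted over the list alone. Of them S1pr1 fell by 1.67 ± 0.18 and Lef1 by 1.58 ± 0.33, whereas Bach2 rose by 1.23 ± 0.25 (list adjusted p = 6.67e-05; adjusted p = 0.388 with an estimated correlation). The largest falls in C57BL/6 were those of the ganglioside synthase St8sia1 (-2.89 ± 0.23), Tdrp (-2.84 ± 0.26), the carboxypeptidase Cpm (-2.47 ± 0.30) and the calcineurin regulator Rcan3 (-2.36 ± 0.38). Slamf1 rose by 0.67 ± 0.19 in C57BL/6 and 0.74 ± 0.19 in Sle1b.BAC, and lost that call in C57BL/6 without unstimulated arrays 1 or 3 or 4 h arrays 1 or 2 (adjusted p = 0.0658, 0.153, 0.0686 and 0.208), and in Sle1b.BAC without unstimulated arrays 2 or 3 or 4 h array 2 (adjusted p = 0.0651, 0.0601 and 0.0548). The count of changed genes was 783 in C57BL/6 without its 4 h array 2, and in Sle1b.BAC 1107 without unstimulated array 1 or 2 and 1154 without 4 h array 2.

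By 24 h, 4158 genes had changed in C57BL/6 (2688 higher, 1470 lower), 4819 in B6.Sle1b (2529 and 2290) and 4975 in Sle1b.BAC (2935 and 2040), of which 2139, 2116 and 2391 changed at least 2-fold. Ribosome biogenesis genes rose with 17 of 18 called in each strain, also 17 adjusted over the list alone, such as Dkc1 (2.48 ± 0.12) and Fbl (1.42 ± 0.14) in C57BL/6. Their list adjusted p was 1.1e-12, 9.04e-13 and 9.03e-13 in C57BL/6, B6.Sle1b and Sle1b.BAC (adjusted p = 0.0467, 0.0412 and 0.0455 with an estimated correlation). Cell cycle genes were called higher in 27, 26 and 27 of 29 cases and 28, 26 and 27 adjusted over the list alone, with the replication helicase genes Mcm5 (2.87 ± 0.29) and Mcm2 (2.76 ± 0.28) and the ribonucleotide reductase Rrm1 (1.70 ± 0.18) in C57BL/6. Their list adjusted p was 1.12e-17, 1.64e-12 and 1.83e-14 (adjusted p = 0.108, 0.148 and 0.13 with an estimated correlation). Glycolysis genes were called higher in 12 of 13 in each strain and 12 adjusted over the list alone, among them Tpi1 (3.68 ± 0.24) and Hk2 (3.53 ± 0.30), with list adjusted p = 4.41e-11, 2.46e-10 and 5.71e-10 (adjusted p = 0.0951, 0.0828 and 0.1 with an estimated correlation). Naive and quiescence genes fell with 11 of 13 called lower in each strain, 1, 1 and 0 higher, and 11 lower adjusted over the list alone, among them S1pr1 (-2.56 ± 0.20) and the antiproliferative gene Tob1 (-2.35 ± 0.19), with list adjusted p = 9.7e-10, 2.89e-09 and 4.4e-11 (adjusted p = 0.108, 0.133 and 0.1 with an estimated correlation).

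Of single genes at 24 h, the chemokines Ccl3 (6.03 ± 0.46, at least 56.0-fold) and Ccl22 (5.66 ± 0.20), the anticoagulant protein S gene Pros1 (5.66 ± 0.26, at least 39.1-fold) and the retinoic acid binding gene Crabp2 (5.48 ± 0.21) rose most in C57BL/6. Crabp2 rose by 5.64 ± 0.19 and 5.81 ± 0.19 and the cytotoxic protease Gzmb by 5.31 ± 0.37 and 4.86 ± 0.37 in B6.Sle1b and Sle1b.BAC. The receptor subunit Ramp3 (-6.43 ± 0.35, -6.13 ± 0.31 and -5.95 ± 0.31) and the G protein regulator Rgs2 (-4.86 ± 0.19, -4.80 ± 0.17 and -4.39 ± 0.17) fell in C57BL/6, B6.Sle1b and Sle1b.BAC. Immediate early genes were lower than in unstimulated cells, with 11 of 21 called lower in each strain and 4, 3 and 4 higher, such as Fos (-3.09 ± 0.31) and Fosl2 (-4.26 ± 0.41) in C57BL/6, and 12, 11 and 11 lower adjusted over the list alone. Myc stayed higher (3.01 ± 0.28; list adjusted p = 7.3e-04, 6.13e-04 and 0.00477, and adjusted p = 0.485, 0.556 and 0.589 with an estimated correlation). The SLAM-associated adaptor Sh2d1a fell (-1.59 ± 0.18, -1.98 ± 0.16 and -1.67 ± 0.16), and Ly9 rose by 1.2 ± 0.25, 0.83 ± 0.23 and 1.19 ± 0.23. Slamf6 fell by 0.89 ± 0.19 in C57BL/6 (adjusted p = 8.1e-04), a fall of the brightest probe set alone, since the mean of its probe sets measured 0.02. T follicular helper genes fell in B6.Sle1b with 8 of 15 called lower and 1 higher, also 8 and 1 adjusted over the list alone, among them the transcription factor Bcl6 (-3.52 ± 0.35), while Cd200 rose by 1.63 ± 0.13 (list adjusted p = 3.43e-04; adjusted p = 0.0828 with an estimated correlation).

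**Figure D4:**
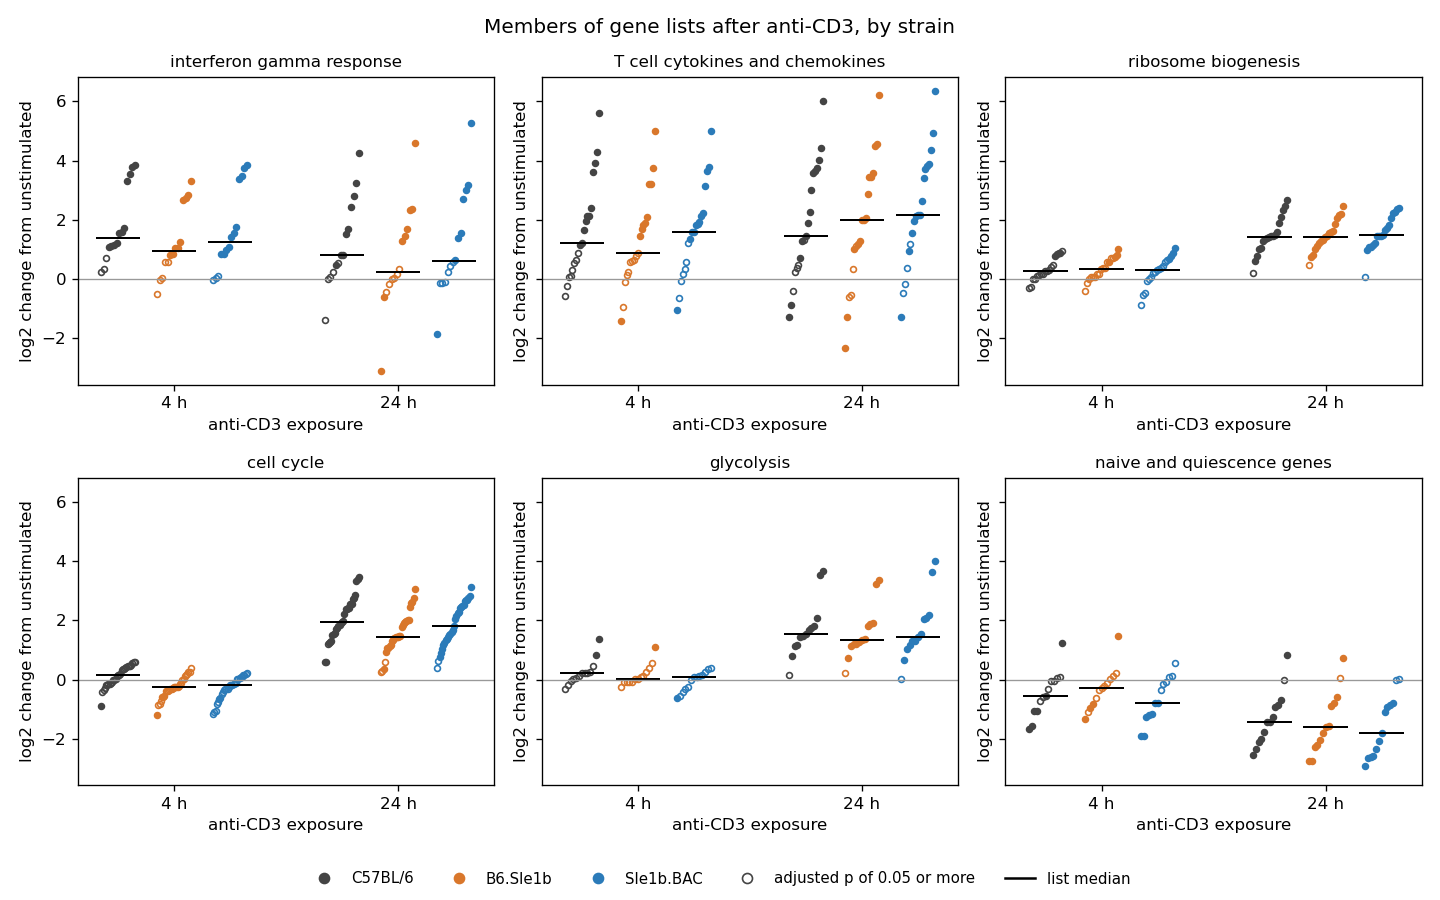
Log2 change from the unstimulated group (y axis) of each member of 6 gene lists at 4 h and 24 h on anti-CD3 (x axis), by strain, with filled points for called genes, open points for the rest and black lines for list medians. The interferon gamma list has 11, 9 and 11 of its 14 members called higher at 4 h, and ribosome biogenesis 17 of 18 in each strain at 24 h.

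Whether strains responded differently was tested as the difference between their responses. Against C57BL/6, limma called 0 genes for the response of B6.Sle1b at 4 h and 0 at 24 h (376 and 821 at an unadjusted p under 0.05). Between Sle1b.BAC and B6.Sle1b it called 0 at 4 h and 1 at 24 h (903 and 873). That gene was Stfa3, whose response was higher by 2.39 ± 0.37 in Sle1b.BAC (adjusted p = 0.0320). Of the groups compared only unstimulated B6.Sle1b had Stfa3 above background, so the difference rests on a fall in B6.Sle1b whose size was not measured exactly, and no response in Sle1b.BAC can be given. The call was lost without any one of 10 of the 12 arrays (adjusted p up to 0.175, without array 2 of B6.Sle1b at 24 h), with only the groups compared, with quantile normalizing again and with every probe set. Without array 2 or array 3 of unstimulated B6.Sle1b, 1 gene was called for the response of B6.Sle1b against C57BL/6 at each time, at 24 h also without array 2 of C57BL/6. For Sle1b.BAC against B6.Sle1b, 1 gene at 4 h and 2 at 24 h were called without array 2 of unstimulated B6.Sle1b. T follicular helper genes responded higher in Sle1b.BAC than in B6.Sle1b at 24 h, with 0 of 15 called and 5 adjusted over the list alone (adjusted p = 5.56e-06; adjusted p = 0.039 with an estimated correlation). A response subtracts the unstimulated level, where this list was lower in Sle1b.BAC on the same arrays. At 24 h itself 0 of 27 lists shifted between these strains, so this result is not separate from the unstimulated difference. The interferon gamma list responded lower in B6.Sle1b than in C57BL/6 at 4 h, with 0 of 14 called, 1 adjusted over the list alone and a median of -0.52 (adjusted p = 4.9e-11; adjusted p = 0.0567 with an estimated correlation). The type I interferon list responded lower there at 24 h, with 0 of 17 called, 1 adjusted over the list alone and a median of -0.92 (adjusted p = 1.31e-08; adjusted p = 0.442 with an estimated correlation). At 4 h the type I list also shifted lower (camera adjusted p = 0.0178, and 0.866 with an estimated correlation), but turned to higher without the 3 dim arrays (camera adjusted p = 0.573). Both interferon lists were higher in unstimulated B6.Sle1b, which the response subtracts, so these lower responses are not separate from that difference.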

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

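The tests of the 3 patterns weighed here were chosen after their results had been seen; the counts of other splits of the arrays were planned before. The response of Stfa3 to 24 h of anti-CD3 differed between Sle1b.BAC and B6.Sle1b by log2 2.39 in a test of the difference itself, but only unstimulated B6.Sle1b lay above background there, so the size is not exact, and the call was lost without any one of 10 of the 12 arrays, with only the groups compared, with quantile normalizing again and with every probe set. Probe sets unnamed here, outside the gene comparisons, also carried differences over the 3 time points, with 29 called between B6.Sle1b and C57BL/6, 13 between Sle1b.BAC and B6.Sle1b and 30 between Sle1b.BAC and C57BL/6. One of them was higher by 1.88 ± 0.18 in B6.Sle1b and 1.87 ± 0.18 in Sle1b.BAC than in C57BL/6.

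The Slamf6 probe sets moved apart between the congenic lines and C57BL/6. Array brightness is argued against, since the smallest absolute difference of the 3 probe sets was still 1.39 with brightness as covariate. A sequence difference that strengthens binding in the congenic lines was not tested. One that weakens it is argued against for the rising probe set, by its direction alone (1.38 higher there). For the falling probe sets it stays open, as the difference of the brighter one changed by -0.82 from unstimulated to 24 h (SE 0.31, unadjusted p = 0.0151 from limma), which a fixed loss of binding alone need not give, but it was not called over all probe sets. A different use of Slamf6 exons between the strains is a candidate explanation that fits both directions and was not tested, because probe sequences were not used here.

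A set of 6 genes was higher in unstimulated B6.Sle1b than in C57BL/6 and lower again in Sle1b.BAC. Array brightness is argued against by a median difference between Sle1b.BAC and B6.Sle1b of -1.37 with brightness as covariate, with 6 of 6 still called both ways. A single aberrant B6.Sle1b array is argued against by a weakest median of -1.40 when each was left out, although only 4 of 6 were called without array 3. RNA from neutrophils is argued against for the lower values in Sle1b.BAC, as their markers differed by 0.37 (SE over arrays 0.66) where the genes had a median of -1.43. For the higher values in B6.Sle1b than in C57BL/6 (median 1.30) it stays open. There the neutrophil markers were higher too, at a mean log2 of 5.19 ± 1.05 (SD) against 4.00 ± 0.64. Something else shared by the 3 unstimulated B6.Sle1b arrays stays open beside an effect of the added chromosome: on other arrays the median was -0.66 at 4 h, with 6 of 6 below 0, and -0.16 at 24 h, with 4 of 6 below 0.

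Both congenic lines differed from C57BL/6 at 24 genes in the same direction. Chance differences of the shared C57BL/6 arrays are argued against as the whole account, since a median of 7 of them were called in both lines against separate parts of those arrays, and the 24 exceed the 0 to 13 shared by as many top genes in simulations with no strain effect; array brightness is argued against by 24 called with it as covariate. Less RNA from B cells cannot raise the 11 higher genes. For the lower ones it stays open, as the B cell markers had a mean of -0.27 (SE 0.12), with 11 of 14 below 0. The lower genes had a median of -0.67. More RNA from neutrophils stays open for higher genes such as the myeloid gene Lyz2. Neutrophil markers were higher than in C57BL/6 by a mean of 1.21 in B6.Sle1b and 1.39 in Sle1b.BAC. Differences between the colonies outside the interval also stay open, as 19 of the genes lie on chromosomes other than 1, and Nnt, higher in both lines, is a gene with a known deletion in the C57BL/6J substrain. The interval itself remains a candidate explanation for Slamf6 and its neighbour Tomm40l, whereas Il17a and Prg4, also on chromosome 1, lie beyond the 100 tested genes on either side of Slamf6. For Tomm40l a sequence difference under its probes is not excluded either. Which of these explanations holds for which gene was not tested.

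Other splits of the arrays into groups of the same sizes were fitted in the same way. Over the 3 time points few splits reached the gene counts, if arrays with the same number in a strain are taken as separate, as the splits do. The shares were not adjusted over the comparisons. For B6.Sle1b against C57BL/6, 57 genes were reached in 2 of 100 splits, the real one included, with 1230 in the highest other. For Sle1b.BAC, 14 against B6.Sle1b were reached in 1 of 100 (highest other 1), and 39 against C57BL/6 in 1 of 100 (highest other 2). Chance is argued against for these counts on that condition alone. With strain and replicate number as a random block the counts were 33, 3 and 24, and whole numbers exchanged between strains would give too few splits for a share under 0.05. Lists were counted at the preset correlation. The 15 lists of the first of these were reached in 1 of 100, but the highest other split gave 14. With an estimated correlation 6 of the 15 shifted, so chance is not excluded there. Nor is it for the 11 lists of the second (5 of 100, highest other 12) or the 6 of the last (58 of 100, highest other 14). For the responses chance cannot be excluded for the lists or for the 24 h gene count, and the counts of 0 genes, which every split reaches by construction, decide nothing: 0 genes and 4 lists for B6.Sle1b against C57BL/6 at 4 h were reached in 100 and 84 of 100 splits (highest other 3803 and 16), 0 and 2 for Sle1b.BAC against B6.Sle1b at 4 h in 100 and 96 (highest other 3222 and 13), and 1 and 9 at 24 h in 16 and 23 (highest other 11 and 15). Splits with 1230 to 3803 genes point to a structure of the arrays that the groups do not describe, and what it is was not tested.

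For the comparisons of 3 with 3 arrays, 10 splits are too few for a share under 0.05. The real gene counts and those of the highest other split were 21 and 2794 for B6.Sle1b against C57BL/6 unstimulated (2 of 10 as large), 7 and 0 at 4 h (1 of 10), 14 and 0 for Sle1b.BAC against B6.Sle1b unstimulated (1 of 10), 0 and 0 at 4 h (10 of 10), 0 and 1 at 24 h (10 of 10), and 10 and 1, then 11 and 0, for Sle1b.BAC against C57BL/6 unstimulated and at 4 h (1 of 10 each). For activation they were 1204 and 416 in C57BL/6 at 4 h, 973 and 0 and 4819 and 1 in B6.Sle1b at 4 h and 24 h, and 1808 and 0 and 4975 and 0 in Sle1b.BAC (1 of 10 each). For the lists, in the order of the strain comparisons, they were 15 and 14 (1 of 10), 11 and 10 (1 of 10), 7 and 9 (3 of 10), 10 and 8 (1 of 10), 0 and 10 (10 of 10), 3 and 12 (9 of 10) and 4 and 9 (8 of 10). For activation they were 7 and 15 in C57BL/6 (5 of 10), 10 and 10 (3 of 10) and 11 and 9 (1 of 10) in B6.Sle1b, and 7 and 13 (4 of 10) and 9 and 12 (6 of 10) in Sle1b.BAC.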

How the results depend on the processing

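Of 4098 values of named genes over the alternatives other than leaving out each array, 3788 kept their direction and their side of the threshold, 301 no longer passed it, and 9 turned, all of them Slamf6 under the mean of its probe sets. Kept calls were unevenly spread. In C57BL/6 at 24 h against unstimulated, 43 of 44 named genes kept their calls in every such setting. For B6.Sle1b against C57BL/6 these were 0 of 15 unstimulated, 0 of 7 at 24 h and 10 of 28 over the 3 times. Trend and robust eBayes, and merging the technical arrays with their nearest biological arrays, moved no total count by over 1.5 times. The lower genes alone moved more for B6.Sle1b against C57BL/6 at 24 h, from 3 to 1 and 6. Brightness as covariate, the 3 dim arrays left out, the merged technical arrays, gene-by-gene weights the SLAM family list without Slamf6 or with the mean of its probe sets, and most settings for the genes that reversed were chosen after seeing the data, and all other alternatives were planned. Where a cause is not given here, the cause was not tested.

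With the mean of its probe sets, Slamf6 was lower in B6.Sle1b than in C57BL/6 by -0.49 unstimulated, -1.10 at 4 h, -0.72 at 24 h and -0.77 over the 3 times, lower in Sle1b.BAC than in C57BL/6 by -0.33, -0.84, -0.54 and -0.57, and changed by 0.025 in C57BL/6 at 24 h. The construction shows the cause, as the other 2 probe sets fall. For the SLAM family list with an estimated correlation over the 3 times, adjusted p was 0.498 without Slamf6 and 0.756 with that mean, turned to lower, for B6.Sle1b against C57BL/6 (main 0.043), and 0.679 and 0.86 for Sle1b.BAC against C57BL/6 (main 0.044). With that setting 3 genes were called for B6.Sle1b against C57BL/6 at 24 h (main 7).

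Counts follow the order unstimulated, 4 h, 24 h and mean, and give only those that moved. With array weights whose iterations had not converged, B6.Sle1b against C57BL/6 gave 2613, 161 (4 h) and 267 (mean), Sle1b.BAC against B6.Sle1b 4018, 29 (24 h) and 142 (mean), and Sle1b.BAC against C57BL/6 77 and 3 (4 h). Activation gave 4742 in C57BL/6 at 4 h, 4497 and 8849 in B6.Sle1b at 4 h and 24 h and 7759 in Sle1b.BAC at 24 h, and the responses gave 1310 and 161 for B6.Sle1b against C57BL/6 at 4 h and 24 h and 1262 for Sle1b.BAC against B6.Sle1b at 24 h. These weights are not reliable.

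With gene-by-gene weights, B6.Sle1b against C57BL/6 gave 135, 55 (4 h) and 117 (mean), Sle1b.BAC against B6.Sle1b 1053, 494, 3 and 533, and Sle1b.BAC against C57BL/6 31, 630 (4 h) and 286 (mean). Activation at 4 h gave 3300 in C57BL/6, 2326 in B6.Sle1b and 5273 in Sle1b.BAC, and the responses 1 and 7 for B6.Sle1b against C57BL/6 and 365 and 90 for Sle1b.BAC against B6.Sle1b. These counts depend on the order in which genes enter: over 20 shuffled orders, B6.Sle1b against C57BL/6 unstimulated gave 124 to 356, Sle1b.BAC against B6.Sle1b 1010 to 1770 unstimulated, 381 to 1044 at 4 h and 3 to 12 at 24 h, and the 4 h response of B6.Sle1b against C57BL/6 1 to 48. Sle1b.BAC against C57BL/6 gave 665 to 1244 at 4 h and 345 to 412 over the 3 times, Sle1b.BAC against B6.Sle1b 541 to 738 over the 3 times, and its responses 406 to 994 at 4 h and 84 to 229 at 24 h. B6.Sle1b against C57BL/6 gave 60 to 83 at 4 h, and activation at 4 h 3475 to 3809 in C57BL/6. Several counts of the order used here thus lie below every shuffled order.

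With array brightness as covariate, B6.Sle1b against C57BL/6 gave 55, 16, 12 and 118, Sle1b.BAC against B6.Sle1b 96 and 83 (mean), and Sle1b.BAC against C57BL/6 22, 210, 11 and 154. Activation at 4 h gave 2563 in C57BL/6 and 2215 in B6.Sle1b, and the 24 h responses 5 for B6.Sle1b against C57BL/6 and 7 for Sle1b.BAC against B6.Sle1b. Lists shifted numbered 8 for B6.Sle1b against C57BL/6 at 24 h, 5 for Sle1b.BAC against C57BL/6 unstimulated, and 5 and 4 for the responses of Sle1b.BAC against B6.Sle1b at 4 h and 24 h. Near Slamf6 the exact p for Sle1b.BAC against C57BL/6 was 0.00104 (main 0.104), and 25 genes, not 7, reversed over the 3 times and 23, not 6, unstimulated. Over the 3 times 2 reversed with strain and replicate number as a random block, 3 with only the groups compared, 3 with centring on the median, 46 and 38 with the 2 kinds of array weights and 3 to 8 without each array. Unstimulated, 10 reversed with replicate number as a block, 0 with only the groups compared, 3 without dim genes, 10 with quantile normalizing again, 1673 and 90 with the array weights and 4 to 9 without each array.

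Without the 3 dim arrays, B6.Sle1b against C57BL/6 at 4 h gave 15, Sle1b.BAC against B6.Sle1b 2 at 4 h, 1 at 24 h and 41 over the 3 times, and Sle1b.BAC against C57BL/6 at 4 h 23. Activation at 4 h gave 2400 in C57BL/6 and 2011 in B6.Sle1b, and the responses 1 and 2 for B6.Sle1b against C57BL/6 and 1 and 6 for Sle1b.BAC against B6.Sle1b. Lists shifted numbered 5 for Sle1b.BAC against B6.Sle1b at 4 h, 6 for Sle1b.BAC against C57BL/6 unstimulated and 5 for the 4 h response of Sle1b.BAC against B6.Sle1b, and the exact p near Slamf6 for Sle1b.BAC against C57BL/6 was 1.75e-04.

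With only the groups compared, and so fewer arrays behind the spread, B6.Sle1b against C57BL/6 gave 0, 2, 0 and 30, Sle1b.BAC against B6.Sle1b 0 and 6 (mean), Sle1b.BAC against C57BL/6 1, 0 and 2 (24 h), C57BL/6 474 at 4 h and 2579 at 24 h, B6.Sle1b 351 at 4 h, and the 24 h response of Sle1b.BAC against B6.Sle1b 0. Quantile normalizing again gave 34 and 11 (4 h) for B6.Sle1b against C57BL/6, 24 over the 3 times for Sle1b.BAC against B6.Sle1b, 42 at 4 h for Sle1b.BAC against C57BL/6, and 0 for that response. Centring on the median gave 3 at 4 h and 3 at 24 h for B6.Sle1b against C57BL/6, and 8 and 6 (mean) for Sle1b.BAC against B6.Sle1b. Leaving out dim genes gave 7 for Sle1b.BAC against B6.Sle1b unstimulated and 0 for its 24 h response. Every probe set gave 18 for Sle1b.BAC against C57BL/6 at 4 h, 1 for the 4 h response of B6.Sle1b against C57BL/6 and 0 for the 24 h response of Sle1b.BAC against B6.Sle1b. All 28 arrays gave 45 (12 higher, 33 lower) for B6.Sle1b against C57BL/6 at 24 h, and 11 (24 h) and 65 (mean) for Sle1b.BAC against C57BL/6. The technical pair averaged as 1 array gave 13 for B6.Sle1b against C57BL/6 at 24 h.

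Replicate numbers were not taken to pair the samples, since the labels do not state a pairing. Pairs of arrays with the same number in a strain had a mean correlation of 0.195 (lowest -0.358, 15 of 25 over 0.1), against -0.0953 for other numbers (11 of 50 over 0.1), and 17 of 26 arrays correlated best with their own number. With brightness removed the means were 0.0533 and -0.0273. Something shared by number is therefore not excluded. The p-values over the 3 time points, which take arrays with the same number as separate, may then be too small. With replicate number as a block, B6.Sle1b against C57BL/6 at 24 h gave 4 genes and 8 lists, 10 genes reversed unstimulated, and no other count moved by over 1.5 times. With strain and replicate number as a random block (correlation 0.154), the counts over the 3 times were 33 for B6.Sle1b against C57BL/6, 3 for Sle1b.BAC against B6.Sle1b and 24 for Sle1b.BAC against C57BL/6.

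With an estimated correlation, the lists shifted numbered 6, 1, 0 and 6 for B6.Sle1b against C57BL/6 (main 15, 11, 5 and 15), 1, 0 and 0 (mean) for Sle1b.BAC against B6.Sle1b (main 7, 10 and 11), 0, 0, 0 and 3 for Sle1b.BAC against C57BL/6 (main 3, 4, 12 and 6), 2 at 4 h and 1 at 24 h in each strain's activation, 0 and 0 for the responses of B6.Sle1b against C57BL/6, and 0 and 1 for those of Sle1b.BAC against B6.Sle1b.

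Leaving out each array in turn gave 11 to 25, 4 to 7, 1 to 5 and 27 to 52 genes for B6.Sle1b against C57BL/6, 5 to 32, 0 to 3 (24 h) and 4 to 19 (mean) for Sle1b.BAC against B6.Sle1b, and 7 to 12, 3 to 19, 1 to 6 and 21 to 40 for Sle1b.BAC against C57BL/6. Activation gave 783 to 1433 and 3036 to 4396 in C57BL/6 at 4 h and 24 h, 690 to 1139 and 4045 to 5562 in B6.Sle1b and 1107 to 2261 and 4252 to 4617 in Sle1b.BAC, and the responses gave 0 to 1, 0 to 1, 0 to 1 and 0 to 2. When 1 of the 2 arrays of C57BL/6 at 24 h was left out, the lone array was assumed to vary like those of the other groups.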

Other observations

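Other gene groups moved between the unstimulated state and 24 h on anti-CD3. Memory and effector genes were lower, with 16, 18 and 14 of 24 called lower and 3, 3 and 4 higher in C57BL/6, B6.Sle1b and Sle1b.BAC, and 17, 18 and 15 lower adjusted over the list alone (adjusted p = 1.2e-07, 1.63e-06 and 2.36e-05; adjusted p = 0.108, 0.148 and 0.234 with an estimated correlation). In C57BL/6 the death ligand Fasl fell by 2.54 ± 0.29 and the interleukin 18 receptor Il18r1 by 2.17 ± 0.15, while Gzmb rose by 4.36 ± 0.41. Cytokine genes were called higher in 12, 13 and 14 of 19 and 13, 14 and 15 adjusted over the list alone, with Lta at 3.64 ± 0.24 in C57BL/6 (adjusted p = 9.91e-07, 1.52e-06 and 6.2e-09; adjusted p = 0.142, 0.148 and 0.111 with an estimated correlation). Cholesterol synthesis genes were called higher in 8, 7 and 8 of 13, as many adjusted over the list alone, with the isomerase Idi1 at 2.22 ± 0.14 (adjusted p = 0.00202, 0.0243 and 8.42e-04; adjusted p = 0.329, 0.556 and 0.329 with an estimated correlation). Amino acid and one-carbon genes shifted higher in C57BL/6 and B6.Sle1b, with 5 and 4 of 13 called and 6 and 4 adjusted over the list alone, and the serine enzymes Psat1 (3.05 ± 0.20) and Shmt2 (2.62 ± 0.32) in C57BL/6 (adjusted p = 0.0286 and 0.0264; adjusted p = 0.329 and 0.347 with an estimated correlation).

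At 4 h, ribosome biogenesis genes were already called higher in 3, 4 and 4 of 18, and 7 in each strain adjusted over the list alone (adjusted p = 8.08e-04, 6.64e-06 and 0.0104; adjusted p = 0.388, 0.174 and 0.609 with an estimated correlation). Between strains over the 3 time points, regulatory T cell genes were higher in B6.Sle1b than in C57BL/6 with 1 of 14 called, Ctla4, and 6 adjusted over the list alone (adjusted p = 4.46e-05; adjusted p = 0.204 with an estimated correlation). NK cell markers were lower with 1 of 7 called, the receptor gene Klrd1 (-0.63 ± 0.13), and 3 adjusted over the list alone (adjusted p = 1.57e-04; adjusted p = 0.0893 with an estimated correlation). The call of Klrd1 was lost without any one of 13 of the 17 arrays (adjusted p up to 0.165, without array 1 of C57BL/6 at 24 h). Plasma cell markers were higher with 2 of 5 called adjusted over the list alone and none over all genes (adjusted p = 0.00457; adjusted p = 0.14 with an estimated correlation), and so were erythroid markers, none of the 6 called (adjusted p = 0.0262; adjusted p = 0.352 with an estimated correlation). The Sle1b region neighbours did not shift (adjusted p = 0.718), though they were higher in Sle1b.BAC than in C57BL/6 at 24 h with 1 of 34 called and 2 adjusted over the list alone (adjusted p = 0.0157; adjusted p = 0.0798 with an estimated correlation). Monocyte and macrophage markers shifted in 1 contrast, higher in Sle1b.BAC than in B6.Sle1b at 4 h with none of the 15 called (adjusted p = 0.0109; adjusted p = 0.467 with an estimated correlation). TCR signalling genes and the markers of dendritic cells and CD8 T cells shifted in none of the 22 contrasts.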
